A study of Mus musculus with 4 samples.

How the data were processed

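Single cells from C57Bl6 mouse lung were profiled with droplet-based 3' RNA sequencing (10x Genomics). Per the labels' protocols, perfused lungs were digested with collagenase, elastase, dispase and DNase and then with trypsin. Cells were stained for CD45, EpCAM, CD11b, CD11c and podoplanin, and with a viability dye, and were sorted by flow cytometry. The gates are not given in the sources used here. CD45 is the surface protein that marks blood-derived cells. The labels name 4 samples that hold 7 libraries. Each library pools the CD45-positive fraction of 1 code with the CD45-negative fraction of another code of the same number. The codes are M1, M2, F1 and F2, and the labels do not spell out what the letters and numbers stand for. M codes gave the CD45-positive and F codes the CD45-negative fraction in 4 libraries, and the roles were swapped in the other 3. The labels do not say whether the sequenced mice had been given house dust mite extract or podoplanin-Fc, which the study used elsewhere.

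The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and droplet, with no normalization in the files. Reads were processed with kallisto against mm10, per the submitters' processing notes. Versions, settings, gene annotation release and any filter before deposit are not given in the sources used here. The labels' protocols name v2 chemistry of the 3' kit, while the barcode list of each library is longer than the list that goes with that chemistry. Each matrix holds 31053 gene entries and all droplets, empty ones included. All columns of per-sample values were used. The authors' cell types were not among the sources used here, so classes were rebuilt.

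Droplets with at least 1000 UMIs, at least 300 genes and at most 15% mitochondrial UMIs were kept as cells. Doublets were called per library with a score of the Scrublet type written here, because the planned program was not installed. Simulated doublets were added to each library, and the cells of highest score were removed at 0.8% per 1000 cells. This took out 984 of 28725 cells, or 3.43%. Counts were scaled per cell and logged, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was clustered with Leiden at a resolution of 1. The 180 genes of the 11 gene lists were held out of the clustering, so that no list gene defined a cluster it was then compared between. Clusters were named from 22 lists of 523 marker symbols, of which 8 were not found among the gene names. A cluster needed at least 3 detected markers of the class, and markers of that class had to lead among its top 50 and top 10 genes by fold. The rules for clusters with markers of several classes, and a minimum share of 0.25 of the markers detected, were added after the clusters had been seen. Of 42 clusters, 4 with 497 cells stayed unnamed, and 21 classes were named. Names below stand for cells that are like the named type by these markers.

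Cells were given to a code through their class: a cell of a blood-derived class belongs to the library's CD45-positive code and any other cell to its CD45-negative code. Raw counts were summed per class and code over libraries. A class entered a class comparison in codes with at least 10 of its cells, with at least 3 such codes, and the M versus F comparison with at least 30 cells in each code. Repeat libraries of 1 code were summed and counted once. The labels do not say whether a code is 1 mouse, so p-values measure the spread between these 4 codes, which may be partly technical.

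The alveolar type 2 (AT2) and type 1 (AT1) classes were compared with edgeR's quasi-likelihood test on summed counts, with TMM scaling, filterByExpr and the code as a block. Each class was compared with the mean of the other classes of its CD45 fraction in the same way, over 9 CD45-negative and 10 CD45-positive classes. This mean is taken over log2 levels with equal weight, so classes near 0 pull it down. A class can thus lie above it while its CPM is below the plain mean of the others. M and F codes were compared within 14 classes, 2 codes against 2, with edgeR and no block. For M against F across both fractions, limma with trend and robust settings was fitted to log2 CPM (prior count of 2), averaged over classes with equal weight, with terms for fraction and library set. The library set says whether M or F codes gave the CD45-positive cells, so its term also holds any M and F difference that differs between the fractions. The filter for this fit first ignored the M and F grouping, which removed Y-linked genes and Tsix. The grouping was put in after that result had been seen. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Gene lists were tested with fry, which asks whether genes move one way on balance, and its mixed form, which asks whether they move either way. Neither sets a list against other genes. Camera with an estimated correlation between genes was the alternative. It does set a list against the other genes, so it asks another question than fry. Its p-values are not a correction of those of fry. Class shares were compared with a two-sided exact permutation test.

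The lists cover the podoplanin and CLEC-2 axis, epithelial alarmins, IL-33 receptor signalling, MHC class II, interferon response, dissociation stress, lipid synthesis, transitional epithelium, adhesion, cell cycle and sex-chromosome genes. Named genes follow a fixed rule. Il33, Pdpn, Clec1b and Il1rl1 are always named. From each list, up to 4 members of largest change past the threshold with 1 sign in every code are taken, and up to 1 that did not pass. For M versus F, the sex-chromosome list, up to 5 genes per class of largest change without overlap between the codes, and genes past the threshold in at least 3 classes are taken. Across fractions, the 10 genes of smallest p per term are taken. A gene that the rule names is not reported here. The lists, markers, rule and planned tests were fixed before the data were examined; tests and settings chosen later are said to be so.

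CPM values are given as the mean and SD over codes. Shares of cells with a UMI were computed after each cell was thinned to 1000 UMIs. Intervals are 95%. Those of counts, count ratios and shares of calls are exact and cover counting error only, with a floor of 3 counts for a value of 0. Those of the shares that platelet and AT2 markers account for come from resampling the markers. They cover the spread between markers only. Free RNA was profiled from droplets under 100 UMIs. Its share in a class was estimated from the 20 most abundant free transcripts among the other fraction's markers, and subtracted in an alternative. Alternatives also covered UMI minimum, mitochondrial limit, doublets, clustering resolution, filter, scaling, DESeq2, replicate blocks, a correlation between the fractions of a code and leaving out each code.

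The tests were run on simulated counts with 200 changed genes. For AT2 against AT1 (10250 genes), 51.6% of 2-fold, 95.3% of 4-fold and 100% of 8-fold changes were recovered, and 10.5% of calls were false. Both classes had the same simulated profile apart from the 200 genes, whereas 4636 genes passed in the real comparison. These shares therefore do not carry over to it. For M versus F in alveolar macrophages (11270 genes), the recovered shares were 83.3%, 93.8% and 98.5%, with 8.59% false calls, and in neutrophils (3409 genes) 50%, 92.7% and 100%, with 4.08% false. Across fractions (11672 genes), 95.5% of 2-fold and 100% of larger changes were recovered, with 3.55% false. In that run the changed genes were drawn only from those with most counts. Every gene had the same dispersion, and a code had no effect shared over its classes. These shares therefore do not measure recovery in the real fit across fractions. For a class against the rest, changes were put into AT2 cells and into alveolar macrophages only. Of 2-fold changes, 93.2% were recovered over 12735 genes of CD45-negative cells, and 95.5% over 11316 genes of CD45-positive cells. False calls made up 3.85% and 3.09%. Smaller classes were not simulated in this comparison, and here too the classes had the same profile apart from the changed genes. In the simulated list test the 1 moved list was called and none of the 10 unmoved ones. The unmoved lists held only unchanged genes, whereas 4636 of 10250 genes passed in the real comparison of AT2 and AT1. This run therefore does not show how often fry calls a list that is like the other genes.

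Work was done with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0). Coordinates are from GENCODE M21 on mm10, matched by the Ensembl identifiers in the files.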

Results

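The series concerns the release of the alarmin IL-33 by lung epithelial cells and its control through podoplanin and its receptor CLEC-2. The data are transcript counts of single lung cells in 7 libraries from 4 labelled samples. By arrangement, 2 samples hold M cells as the CD45-positive and F cells as the CD45-negative fraction, 1 holds the swapped arrangement, and 1 holds 1 library of each arrangement. Libraries with CD45-positive cells of M1 held 48251844 and 44370489 UMIs, those of M2 48640477 and 30781114, that of F1 43367119, and those of F2 43069937 and 40232897. Droplets under 100 UMIs took 7.85 to 11.3% of a library's UMIs. The 27741 cells had a median of 6432 UMIs, with library medians from 5184 to 7798. The CD45-negative fractions of M1, M2, F1 and F2 gave 1428, 2939, 4319 and 2936 cells, and the CD45-positive fractions 5745, 3757, 1801 and 4296. Libraries of the same code differed by more than the counting noise of UMIs in all 45 class sums compared (chi-square per degree of freedom 1.52 to 9.70, median 2.63). The 262 pairs of different codes gave 1.41 to 13.7, with a median of 3.44. This chi-square does not allow for differences between the cells drawn, so it cannot show a difference between libraries beyond those. Counts of libraries of the same code were summed and each code was counted once.

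The labels were first checked with genes of the sex chromosomes. Xist, the noncoding RNA of the inactive X chromosome, lies on mm10 chromosome X from 103460366 to 103483254. It stood at 817 ± 323 CPM in 37 class sums of F codes and at 33.9 ± 52.8 CPM in 39 sums of M codes. The Y-linked genes Ddx3y (chromosome Y, 1260771 to 1286629), Eif2s3y, Kdm5d and Uty together stood at 9.36 ± 9.33 CPM in F and 190 ± 64.6 CPM in M sums. Every F code lay above every M code for Xist in 19 of 19 classes, and the Y-linked genes showed the reverse order in 19 of 19. Cells with UMIs of both Xist and a Y-linked gene made up 0.984 to 2.24% of a fraction. Cells with UMIs of only the other letter's marker made up 0.836 to 2.52%. Among M sums, Xist reached 84.9 and 197 CPM in AT1 cells of M1 and M2 and 261 CPM in lymphatic endothelial cells of M1. Free RNA, doublets and cells given to the wrong code were not told apart here.

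AT2 cells, which make surfactant, and AT1 cells, the flat cells of gas exchange, were compared first because the study is about IL-33 from epithelium that also displays podoplanin. The classes held 2370 AT2 and 206 AT1 cells. Il33 (ENSMUSG00000024810, chromosome 19 from 29925114 to 29960718), the gene of the alarmin, stood at 325 ± 34.9 CPM in AT2 and 1.05 ± 1.32 CPM in AT1 cells (SD, n = 4 codes). With 13206 and 2 counts, the ratio was 222 with a counting interval of 61.5 to 1834. Pdpn (ENSMUSG00000028583, chromosome 4 from 143267431 to 143299564), which encodes podoplanin, had the opposite pattern, with 1.81 ± 1.2 CPM in AT2 and 879 ± 88.8 CPM in AT1 cells. Its log2 fold change was −8.24 ± 0.34 (SE, AT2 minus AT1), with an edgeR adjusted p of 5.56e-08. Both genes had their direction in 4 of 4 codes.

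Of 10250 genes tested, 2688 were higher in AT2 and 1948 higher in AT1 cells, and 5177 had an unadjusted p under 0.05. Among the 9471 genes that had not served for clustering, 2440 were higher in AT2 and 1606 in AT1 cells. Scaling by library totals alone turned the balance, to 1419 higher in AT2 and 4302 higher in AT1 cells (1222 and 3907 outside the clustering genes). The median log2 fold change of all tested genes was 0.11 with TMM scaling and −0.54 with totals alone. The changes below are relative to the TMM scale.

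Genes of lipid and sterol synthesis, the supply of surfactant lipid, were mostly higher in AT2 cells: 17 of 18 measured genes rose and 1 fell. Fasn, the fatty acid synthase, rose by 5.01 ± 0.20 on the log2 scale (SE), from 26.3 ± 12.6 to 625 ± 47.3 CPM, with an edgeR adjusted p of 4.17e-62. The desaturase gene Fads1 rose by 5.11. The list moved up by fry, adjusted p = 0.00510. Camera with an estimated correlation, which asks whether the list stands out from the other genes, gave an adjusted p of 0.230. For all lists below, a p-value "with an estimated correlation" is that of camera. The dissociation list of heat shock and immediate early genes had 19 of 21 members higher in AT2 cells and 1 lower (adjusted p = 0.00127, and adjusted p = 0.143 with an estimated correlation). Ier2 rose by 3.09 to 389 ± 75.8 CPM and Hspa1b, a chaperone gene nearly identical to Hspa1a and so uncertain on its own, by 3.67 to 208 ± 135 CPM. Hsp90aa1 did not pass and stood at 1073 CPM in AT2 and 1542 CPM in AT1 cells. With totals alone it was lower in AT2 cells, at −0.54. In the cell cycle list 4 of 7 measured members rose and none fell (adjusted p = 0.0241, and adjusted p = 0.541 with an estimated correlation). The tubulin-binding gene Stmn1 stood at 291 CPM in AT2 and 49.6 CPM in AT1 cells.

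Interferon response genes went the other way: 8 of 12 measured members were lower in AT2 than AT1 cells and none was higher (adjusted p = 0.00329, and adjusted p = 0.147 with an estimated correlation). Adjusted over the list alone, 9 were lower. Ifit3, an antiviral effector, stood at 0.291 ± 0.369 CPM in AT2 and 124 ± 14.8 CPM in AT1 cells, a log2 fold change of −7.86 ± 0.36 (SE, edgeR adjusted p = 2.01e-41). Its neighbour Ifit1 stood at 0.188 and 58.4 ± 48.7 CPM. For Ifit2, with 3 counts in AT2 cells, the ratio was 327 with a counting interval of 103 to 1667. In the adhesion list 9 of 14 members were lower in AT2 cells and 3 higher (adjusted p = 0.000703, and adjusted p = 0.143 with an estimated correlation). Lama3, a laminin chain, changed by −5.41 ± 0.17 and the integrin gene Itga3 by −3.95, while the E-cadherin gene Cdh1 did not pass on the TMM scale (−0.17, adjusted p = 0.344) and passed with totals alone at −0.82. In the podoplanin and CLEC-2 list 8 of 13 were lower in AT2 cells and 2 higher (adjusted p = 0.000703, and adjusted p = 0.143 with an estimated correlation). Besides Pdpn these included Msn, whose product moesin links podoplanin to actin, at 98.4 ± 9.88 CPM in AT2 and 1250 ± 213 CPM in AT1 cells, and the tetraspanin gene Cd9, at 483 and 2685 CPM.

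Of the alarmin list 4 of 7 measured genes were higher in AT2 cells and none lower (adjusted p = 0.0129, and adjusted p = 0.421 with an estimated correlation). Csf2, the gene of the growth factor GM-CSF, stood at 20.0 ± 2.82 and 2.73 ± 5.46 CPM. The neutrophil chemokine gene Cxcl1 did not pass, at 26.8 and 23.9 ± 34.2 CPM. Without M1 it passed at 2.78. In the IL-33 receptor list 5 of 9 rose and 1 fell (adjusted p = 0.0429, and adjusted p = 0.633 with an estimated correlation). Among them Areg, the gene of the repair factor amphiregulin, stood at 321 ± 132 CPM in AT2 and 13.9 ± 9.64 CPM in AT1 cells. The adaptor gene Myd88 rose by 1.15, but by 0.50 with totals alone, where it did not pass (edgeR adjusted p = 0.151).

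Lists of mixed direction were MHC class II, transitional epithelium and sex-chromosome genes. For MHC class II 3 of 9 rose and 2 fell, with fry adjusted p = 0.425 for 1 direction and 0.00628 for either, and adjusted p = 0.810 with an estimated correlation. The costimulatory gene Cd86 stood at 0.645 CPM in AT2 and 18.7 ± 11.1 CPM in AT1 cells, and H2-Ab1, which did not pass, at 617 and 710 CPM. Of the transitional list 5 of 12 rose and 4 fell, with an adjusted p of 0.0953 for 1 direction, 0.000995 for either and adjusted p = 0.776 with an estimated correlation. Its median log2 fold change was 0.14 while fry's direction was down. The stress gene Nupr1 rose by 5.52 ± 0.23 and the integrin gene Itgb6 changed by −5.45 ± 0.18. Of the sex-chromosome list 3 of 10 rose and 1 fell (fry adjusted p = 0.0851 for 1 direction and 0.00119 for either, and adjusted p = 0.776 with an estimated correlation). Adjusted over the list alone, the counts of every list other than interferon were those over all genes. RNA of other cells differed between the AT1 sums of the codes. Alveolar macrophage markers summed to 4247 CPM in M1 against 157 to 291 CPM in the others. T-cell markers reached 786 CPM in M2 against 24.7 to 187 CPM, and AT2 markers 9985 CPM in F2 against 1244 to 1695 CPM.

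**Figure D1:**
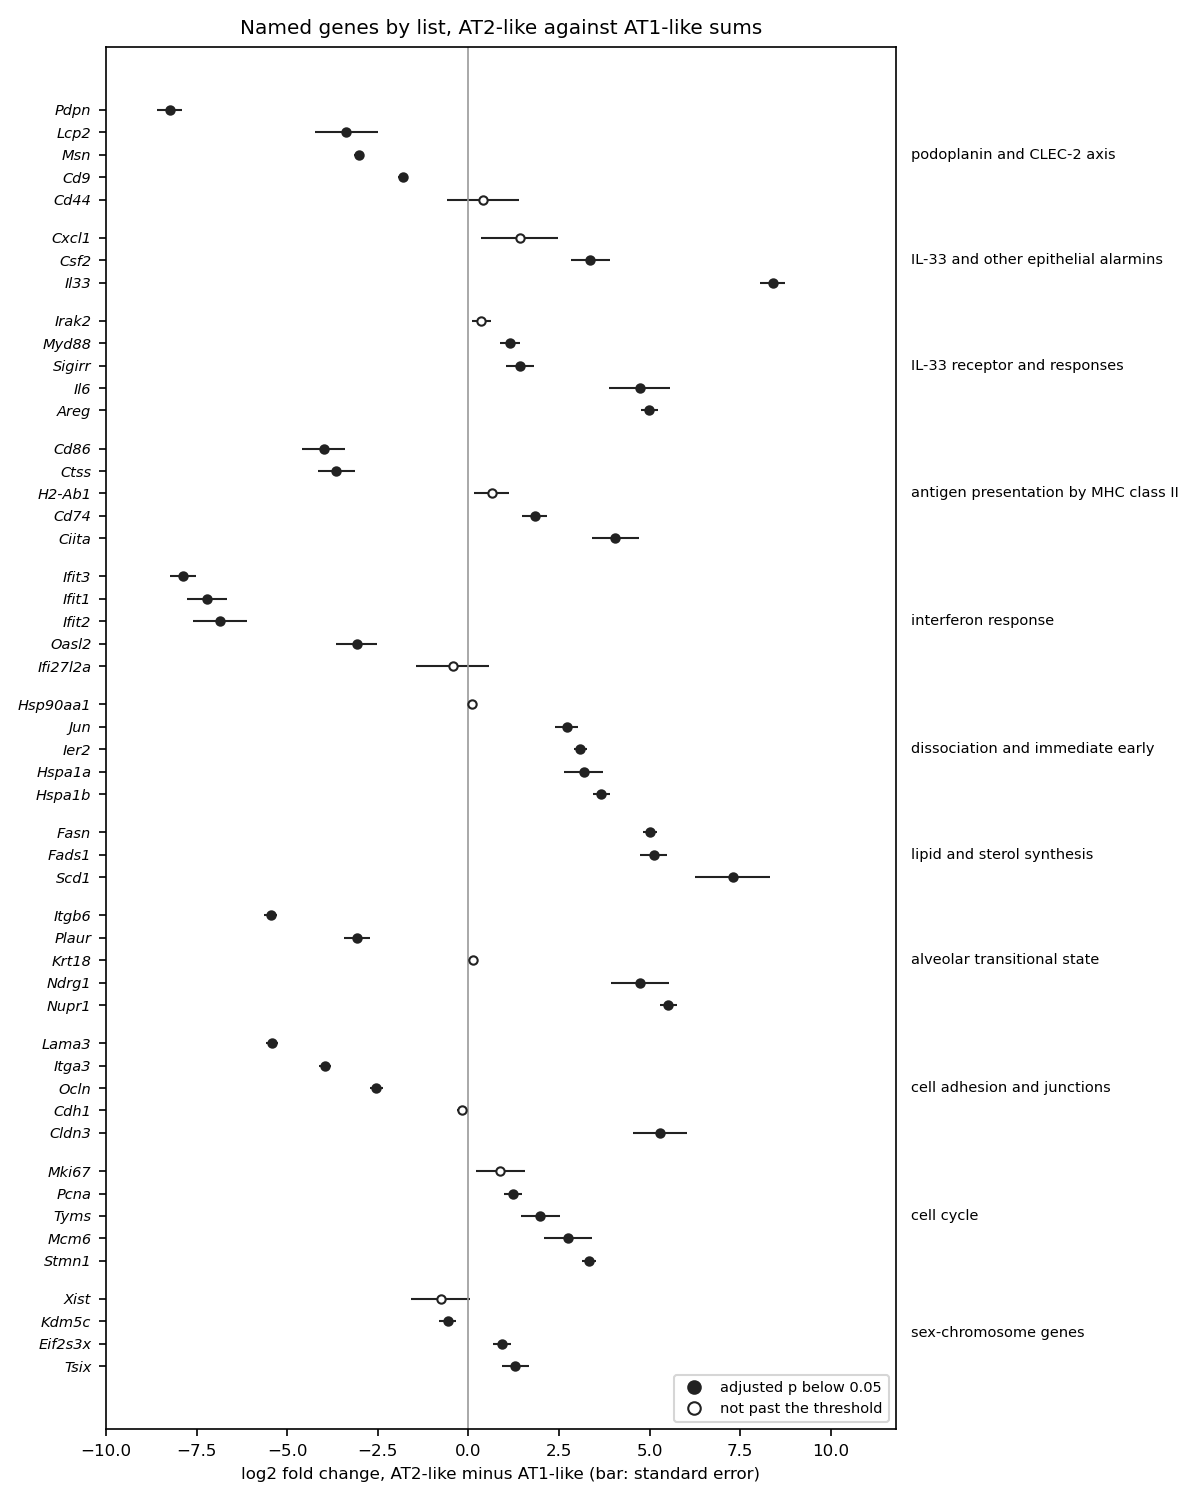
Log2 fold change (AT2 minus AT1, with SE, n = 4 codes) of named genes, grouped by gene list, with filled points for an edgeR adjusted p below 0.05 and open points otherwise. Il33 and Pdpn lie far apart, with Pdpn at −8.24.

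Over all CD45-negative classes, Il33 was higher in AT2 cells than in the mean of the other 8 classes, by 5.84 ± 0.19 on the log2 scale (SE, edgeR adjusted p = 5.41e-20). Mesothelial cells, which line the pleura, followed with 179 ± 39.6 CPM (SD, n = 4 codes) and a difference of 4.14 ± 0.31 (adjusted p = 2.04e-11), from 122 cells. Fibroblasts stood at 38.1 ± 4.33 CPM (1.83, adjusted p = 1.54e-06). Lymphatic endothelial cells ranged from 0 to 90.7 CPM between codes and did not pass (1.29, adjusted p = 0.193). Club cells stood at 3.53 ± 3.28 and blood endothelial cells at 3.36 ± 1.23 CPM. Pdpn was higher in AT1 (6.12 ± 0.14, adjusted p = 5.40e-32), mesothelial (4.50, 307 ± 73.7 CPM) and lymphatic endothelial cells (4.43, 346 ± 63.5 CPM). Its log2 level in fibroblasts (1.89, 53.8 ± 8.38 CPM) and club cells (1.39, 16.2 ± 3.64 CPM) also lay above the mean log2 level of the others. In CPM, club cells stood below AT1, lymphatic endothelial, mesothelial cells and fibroblasts. The ratio of AT1 to fibroblast Pdpn was 16.8, with a counting interval of 15.6 to 18.

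**Figure D2:**
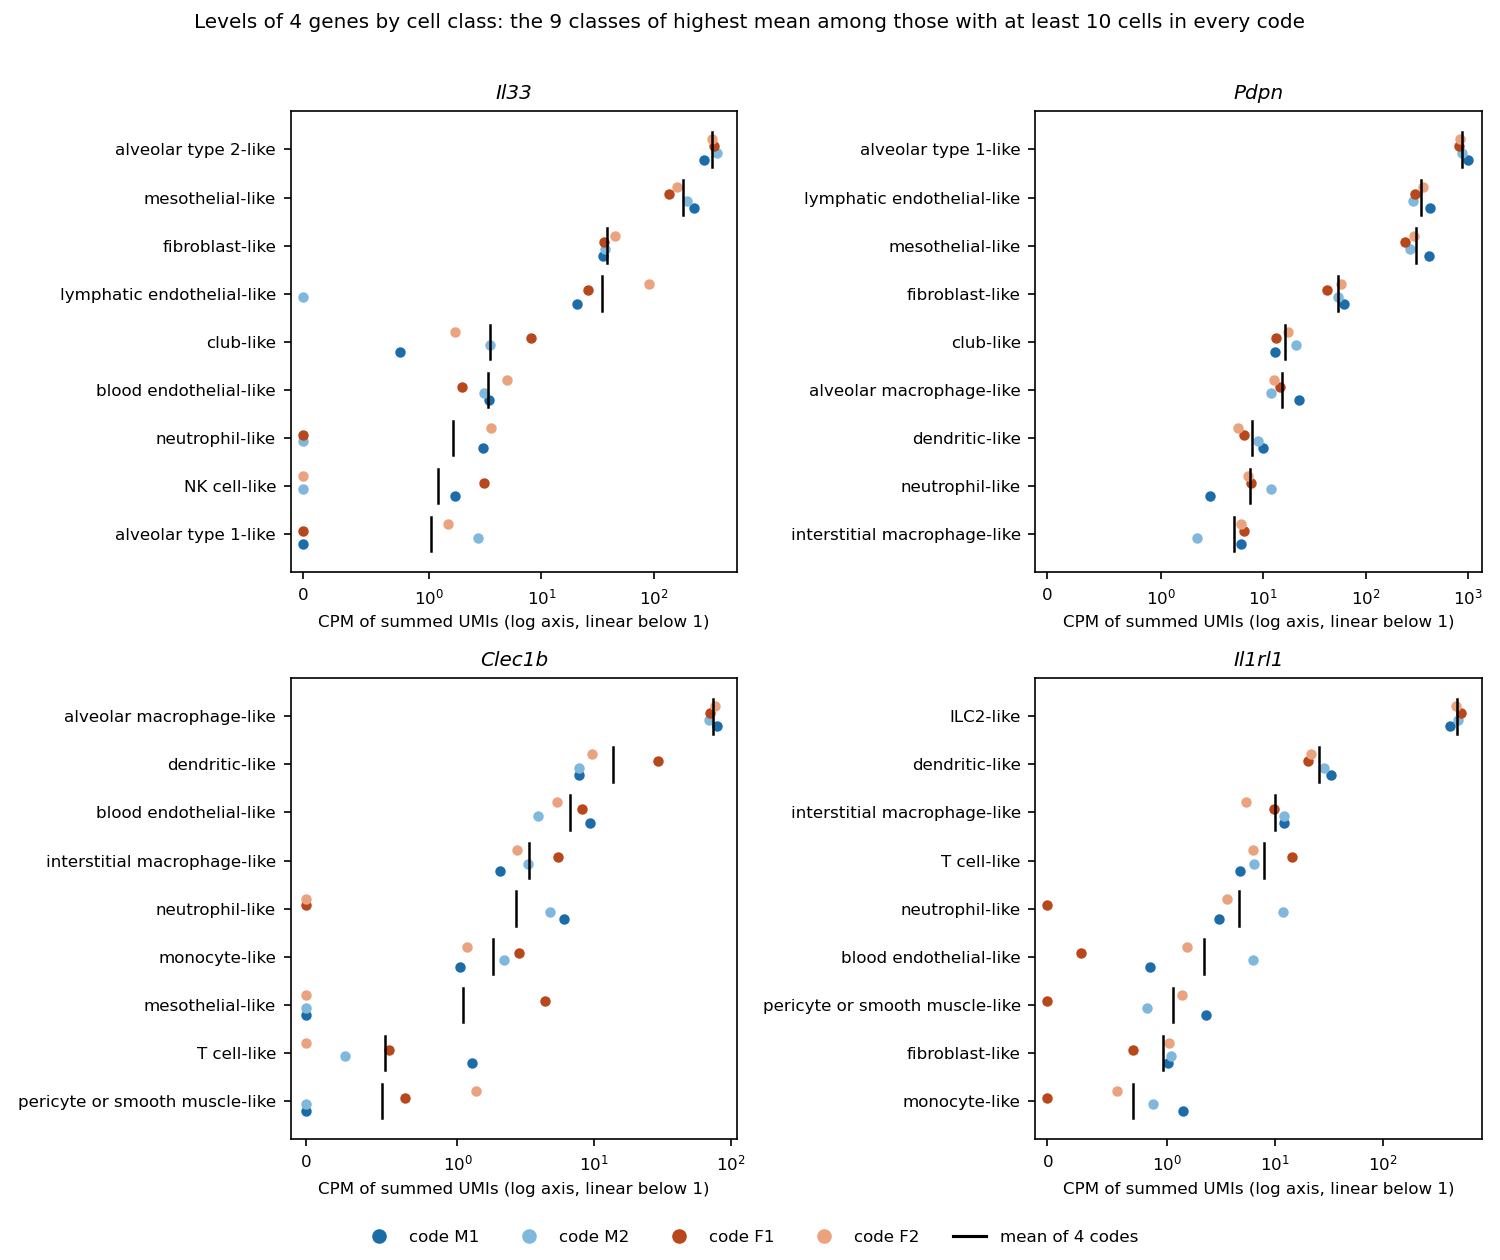
Level of Il33, Pdpn, Clec1b and Il1rl1 in CPM, on an axis that is linear near 0 and logarithmic above, in the 9 classes of highest mean among those with at least 10 cells in every code, with a point per code and a bar at the mean of 4 codes. Among these classes each gene has another leading class: AT2 for Il33 (325 CPM), AT1 for Pdpn (879 CPM), alveolar macrophages for Clec1b (73.9 CPM) and ILC2 for Il1rl1 (482 CPM).

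Clec1b (ENSMUSG00000030159, chromosome 6 from 129397297 to 129409335), which encodes the podoplanin receptor CLEC-2, was higher in alveolar macrophages than in the other CD45-positive classes. It stood at 73.9 ± 4.71 CPM there, a log2 difference of 6.78 ± 0.26 from the mean of the other 9 classes (SE, edgeR adjusted p = 1.62e-19). Dendritic cells came next, at 13.7 ± 10.6 CPM (4.22 ± 0.43, adjusted p = 1.42e-09), with 29.6 CPM in F1 and 7.76 to 9.72 CPM in the others. Interstitial macrophages stood at 3.36 ± 1.47 CPM, and the ratio of alveolar to interstitial macrophages was 23.9 with a counting interval of 17.4 to 33.8. The difference of interstitial macrophages from the rest (1.96, adjusted p = 0.0373) did not pass without M2 (1.92, adjusted p = 0.132) or without F2 (1.85, adjusted p = 0.328), nor under any change of the UMI minimum, mitochondrial limit, doublet removal or clustering resolution. Monocytes had 1.80 ± 0.845 CPM. Il1rl1 (ENSMUSG00000026069, chromosome 1 from 40429570 to 40465415), which encodes the IL-33 receptor chain ST2, was higher in group 2 innate lymphoid cells (ILC2). There it stood at 482 ± 46.5 CPM, a difference of 7.61 ± 0.18 (adjusted p = 5.05e-27). Dendritic cells had 25.8 ± 6.14 CPM (3.07, adjusted p = 4.49e-14), and the ratio of ILC2 to dendritic cells was 18.1 (16.4 to 20.0). In T cells (7.94 ± 4.32 CPM) the difference of 0.92 passed (adjusted p = 0.0209) but not without F1 (0.68, adjusted p = 0.105) or F2 (0.70, adjusted p = 0.131), nor at a Leiden resolution of 2 (0.18, adjusted p = 0.711) or with DESeq2 (adjusted p = 0.0516).

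Pdpn was also found in CD45-positive cells, at 15.4 ± 4.74 CPM in alveolar macrophages (3.75, edgeR adjusted p = 7.82e-19) and 7.77 ± 2.00 CPM in dendritic cells (3.11, adjusted p = 1.13e-12). Il33 stood at 0.411 CPM in alveolar macrophages. In the droplets under 100 UMIs, Il33 stood at 39.8 to 63.6 CPM, Pdpn at 14.8 to 25.9, Clec1b at 11.1 to 21.6 and Il1rl1 at 6.40 to 16.4 CPM. The estimated share of free RNA in a class had library medians from 0.898 to 1.65%, and reached 9.96% in mesothelial and 7.71% in blood endothelial cells of 1 library, whose median was 1.22%.

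At 1000 UMIs per cell, 24.0 ± 2.84% of AT2 cells held an Il33 UMI (SD, n = 4 codes), against 0.212 ± 0.124% of B cells. Without thinning the shares were 88.6% and 0.308%, at median depths of 17035.5 and 3268 UMIs. No cell was below 1000 UMIs, so none was left out. Mesothelial cells reached 13.9 ± 6.45% (61.5% unthinned, median 10161.5 UMIs), and 0 of 206 AT1 cells had one at this depth (up to 1.46%), while 2 had one unthinned. A Pdpn UMI was found in 58.5 ± 5.22% of AT1 cells (87.1% unthinned, median 5355.5 UMIs) and in 0 of 2965 T cells (up to 0.101%, median 5325 UMIs; 9 cells unthinned). The share was 28.1 ± 9.64% in lymphatic endothelial and 25.5 ± 6.89% in mesothelial cells. Clec1b had a UMI in 7.07 ± 0.993% of alveolar macrophages (54.0% unthinned, median 15473 UMIs) and in 0 of 3706 B cells (up to 0.0809%; 1 cell unthinned). Il1rl1 had one in 37.1 ± 6.46% of ILC2 (77.7% unthinned, median 4453.5 UMIs) and in 0 of 2903 alveolar macrophages (up to 0.103%). Unthinned, 14 of these macrophages had one, and the mean of the shares per code was 0.550%.

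M and F codes were compared within 14 classes. Within a class, M and F cells lie in different libraries, so library and letter cannot be told apart there. ILC2 of F codes held more Lif, the gene of a cytokine of the IL-6 family, with 96.2 ± 16.7 CPM against 24.0 ± 12 CPM in M codes (SD, n = 2 codes each; −1.95, edgeR adjusted p = 0.0186, but 0.196 with DESeq2). Lif was higher in F also in alveolar macrophages (−1.37) and dendritic cells (−2.43). Jchain, the joining chain of secreted antibodies, differed most in B cells, with 230 ± 23.9 CPM in F and 2.70 CPM in M codes (−6.25 ± 0.20, adjusted p = 2.10e-19). With cells from 500 UMIs on, the difference was −0.43 and did not pass (adjusted p = 0.945). Cxcl13, a B-cell chemokine, stood at 34.8 ± 10.7 CPM in dendritic cells of F and 2.24 CPM in those of M (−3.91, adjusted p = 0.0303), and the phagocyte receptor gene Vsig4 at 12.7 and 0 CPM. The Cxcl13 call was lost without the library with the highest free RNA share of a single class (−4.01, adjusted p = 0.433; the SE rose from 0.41 to 0.80), and the Vsig4 call without M2 (−9.12 against −9.18 in the full fit, adjusted p = 0.0663). In that class a Cd209a cluster was largest among M cells (47.0% against 36.0% in F) and an Xcr1 cluster among F cells (43.8% against 40.2% in M). A cluster led by Fscn1 held 3.84% of M and 10.1% of F cells. Whether these shares gave the dendritic calls was not tested. In neutrophils 3 of 10 MHC class II genes and the immunoglobulin genes Iglc2 and Ighm were higher in M codes: H2-Eb1 stood at 937 ± 116 against 257 ± 12.1 CPM (1.86, adjusted p = 0.000252) and H2-Ab1 at 896 against 275 CPM, Iglc2 at 143 against 35.0 CPM (2.05, adjusted p = 0.00784) and Ighm at 366 against 134 CPM (1.30, adjusted p = 0.0491). RNA of B cells in these sums was not excluded. Fibroblasts of M had more Cytl1, a cytokine-like gene of cartilage, at 106 ± 1.86 against 21.3 ± 4.82 CPM (2.34, adjusted p = 1.88e-05). Cytl1 did not pass at a Leiden resolution of 0.5 (0.42), a minimum of 2000 UMIs (2.34), a limit of 10% mitochondrial UMIs (1.68) or without doublet removal (1.85). Pericytes or smooth muscle cells of M had more Hspa1b (1149 ± 369 against 342 ± 17.8 CPM). In this class a cluster led by Acta2 held 48.0% of M and 38.7% of F cells, and a cluster led by Hhip 19.6% and 29.6%. Blood endothelial cells of F held S100a8, a neutrophil gene, at 69.0 ± 1.59 against 2.32 ± 2.74 CPM (−5.36, and −7.31 to −4.02 without 1 code). The chemokine gene Cxcl17 was higher in AT2 cells of F, at 44.4 ± 2.28 against 20.3 ± 4.06 CPM (−1.03, adjusted p = 0.00609; −0.87 and adjusted p = 0.0725 without M1). H2-Q7, a class I gene with near-identical copies and so uncertain, was higher in F in monocytes, B cells and alveolar macrophages (−0.89, −0.78 and −1.44). The call was lost in alveolar macrophages without doublet removal (−1.01, adjusted p = 0.539). It was also lost at a like fold and a larger SE after subtraction of free RNA (−1.58, adjusted p = 0.105) and without M1 (−1.43, adjusted p = 0.609) or M2 (−1.43, adjusted p = 0.523), and in monocytes without F2 (−0.90, adjusted p = 0.0532).

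Outside the sex-chromosome list there were 192 such calls over all classes, 56 higher in M and 136 higher in F, on 175 genes. B cells had 44, alveolar macrophages 40 and dendritic cells 40. Club cells had 0 with edgeR (339 genes with an unadjusted p under 0.05) and 0 with DESeq2. With edgeR no sex-chromosome gene passed in club cells either, though Xist and the Y-linked genes did not overlap between M and F codes. The smallest code held 43 club cells, so this 0 does not show that M and F are alike there. Counts moved with the codes: calls higher in M numbered 228, 242, 313 and 142 without M1, M2, F1 and F2, and calls higher in F 193, 352, 797 and 449. B cells had 18 without M1, 289 without F1 and 83 without F2, alveolar macrophages 25 without M1 and 250 without F1, dendritic cells 69 without F1 and 69 without F2. Club cells had 19, 10, 136 and 14. With the code number as a replicate block, 178 calls were higher in M and 376 in F. In fits without a code, a lone code is assumed to vary like the pair. Values of M and F codes did not overlap in 30.6 to 40.7% of genes, where chance gives a share of 0.33. Of the 192 calls 35, or 18.2%, were fixed markers of another class, against 1.84% of all tested pairs of gene and class. In 143 of 192 calls (74.5%), the direction was that of the difference in empty-droplet RNA between the library sets.

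**Figure D3:**
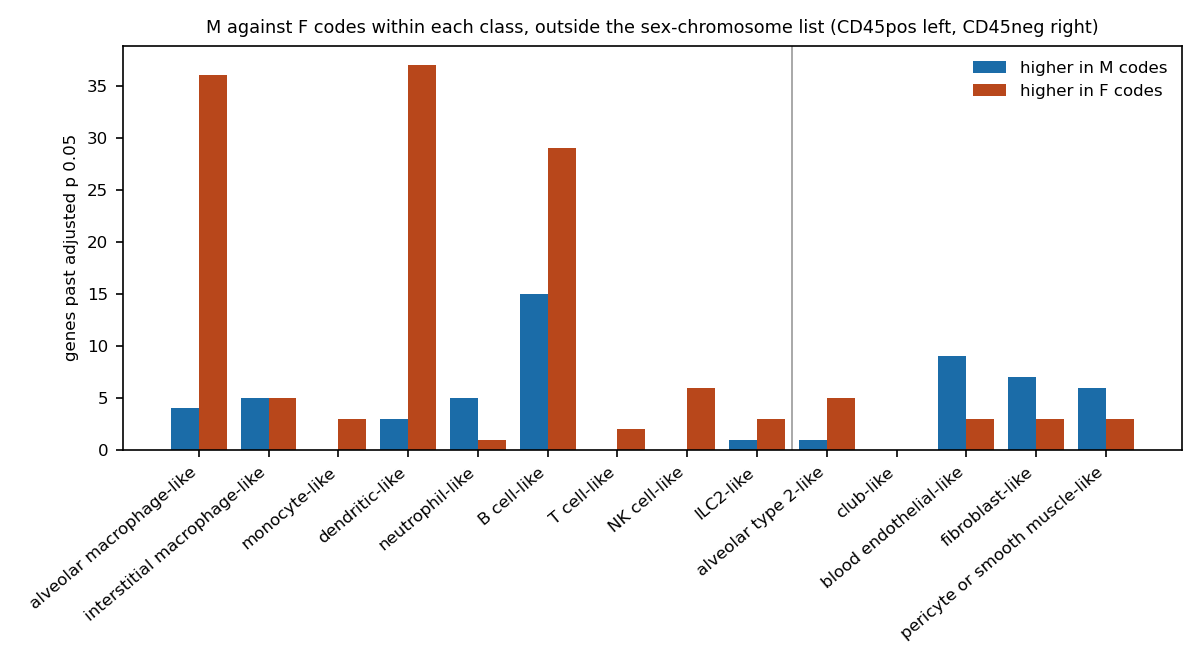
Number of genes past an edgeR adjusted p of 0.05 between M and F codes in each of 14 classes, outside the sex-chromosome list, with bars for genes higher in M (blue) and in F (red). B cells, alveolar macrophages and dendritic cells have 44, 40 and 40 calls, club cells 0.

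Of the gene lists other than sex-chromosome genes, 1 moved one way between M and F: interferon response genes in fibroblasts, lower in M (fry adjusted p = 0.000593, and adjusted p = 0.359 with an estimated correlation). None of its 18 measured genes passed over all genes, and 4 passed adjusted over the list alone. Movement in either direction passed for MHC class II in neutrophils (adjusted p = 0.0431, 3 of 10 genes rose in M) and for the dissociation list in fibroblasts (1.69e-05, 2 of 21 rose in M). It also passed for alarmins in interstitial macrophages (0.0190), and for interferon genes in neutrophils (0.0234), club (0.00861) and blood endothelial cells (0.0358). The same held for lipid synthesis in neutrophils (0.0431) and cell cycle in fibroblasts (0.0356). With an estimated correlation none of these 8 passed (adjusted p from 0.108 to 0.922).

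Across both fractions the library set is crossed with M and F, so both could be fitted. By this design the library-set term is also the difference of M minus F between the fractions, and these cannot be told apart. The fit takes the 8 means of 4 codes as independent values. Of 11618 genes, 6 differed between M and F by limma, all on the sex-chromosome list. Xist was tested and did not pass, though class sums averaged 817 CPM in F and 33.9 CPM in M codes. Adjusted over the list alone, all 10 members passed. The fit over all genes can therefore miss a large difference, and a gene that did not pass may still differ. Ddx3y was higher in M by 4.96 ± 0.11 on the log2 scale (SE, adjusted p = 9.42e-12), and Eif2s3y, Kdm5d and Uty by 4.77, 3.72 and 3.99. Tsix (−3.40) and Eif2s3x (−0.51, adjusted p = 0.0252) were higher in F. The call of Eif2s3x was lost without M1 (−0.44, adjusted p = 0.753), M2 (−0.59, 0.0897) or F1 (−0.50, 0.0844). Tsix overlaps Xist on the other strand, and the strand setting of the counting is not given in the sources used here. Next came the chaperone gene Dnaja1 (0.35) and the X-linked Kdm6a (−0.58), both with an adjusted p of 0.0522. Kdm6a passed without F1 (−0.69, 0.0131). The interferon-induced Ifi27l2a (−0.68, adjusted p = 0.0543) passed without F1 (−0.86, 0.000118), without F2 (−0.50, 0.0236) and without the library with the highest free RNA share of a single class (−0.70, 0.0176). Outside the list 0 of 11608 genes passed in limma, the 1 tool run on these means, and 551 had an unadjusted p under 0.05. With a correlation between the fractions of a code (estimated at 0.0369) the counts were again 6 and 0. Codes of the same number share libraries, and with the number as a replicate block 11 genes passed, 2 of them outside the list, among them Dnaja1 (adjusted p = 0.0120). Without M2, F1 and F2 there were 11, 15 and 20 genes in all and 5, 7 and 14 outside the list. For the library-set term 1 gene passed, Ddx3y (0.93, adjusted p = 0.0134), which may be a difference between the fractions or between the libraries.

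Shares of classes were compared between M and F with an exact permutation test, which cannot go below p = 0.33 with 2 codes against 2. AT2 cells made up 24.5 and 22.6% of the CD45-negative cells in M1 and M2 and 18.6 and 18.8% in F1 and F2 (exact p = 0.33), and blood endothelial cells 20.3 and 20.1% against 23.0 and 22.5%. ILC2 made up 2.35% of the CD45-positive cells in M and 4.55% in F, and monocytes 8.14 and 6.40%. The test could not have passed whatever the shares were, so it leaves differences in share open, and shares depend on the sort and on cell survival.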

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

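The test of whether the AT2 minus AT1 difference itself differs between M and F codes was chosen only after the report's results were seen. Single codes were compared with the other 3 in 68 groups of 4 values, and chance alone sets about 1 group in 20 apart in such a check.

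In 6 groups 1 code stood apart from the other 3. Clec1b in dendritic cells stood at 29.6 CPM in F1 and at 7.76 to 9.72 CPM in the others. In fibroblasts it stood at 1.29 CPM in F1 and at 0 to 0.199 CPM in the others, from 20 counts over all codes. Il33 in fibroblasts stood at 44.5 CPM in F2 and at 35.3 to 36.3 CPM in the others. Pdpn in interstitial macrophages stood at 2.28 CPM in M2 and at 6.11 to 6.53 CPM in the others, and in T cells at 1.65 CPM in F1 against 0.365 to 0.514 CPM. The T cells held only 9 Pdpn counts over all codes, so counting noise was not excluded there. Plasma cells made up 1.05% of the CD45-positive cells in F2 and 0.266 to 0.389% in the others.

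The AT2 minus AT1 difference differed between M and F codes for 23 of 10250 genes (edgeR, 8 with a larger and 15 with a smaller value in M; 422 at an unadjusted p under 0.05). By log2 size, M minus F, the difference was −2.93 for Xist, 1.15 for the immediate early gene Jun, −4.46 for Cxcl1 and −3.99 for Ifi27l2a. In M1 and M2, Xist stood at 84.9 and 197 CPM in AT1 cells and at 7.35 and 20.1 CPM in AT2 cells. RNA of F cells in these AT1 sums was not excluded. The AT1 sum of F2, with 100 cells, held AT2 markers at 9985 CPM, and 5 of the 23 genes are such markers (Sftpd, Lamp3, Napsa, Slc34a2 and S100g). The chemokine gene Cxcl2, picked after its values were seen, stood at 1285 and 303 CPM in AT1 cells of M1 and M2 and at 16.5 and 38.6 CPM in those of F1 and F2. The AT1 sum of M1 also held alveolar macrophage markers at 4247 CPM, against 157 to 291 CPM in the others, so RNA of other cells was not excluded.

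Cells outside the comparisons carried clear signals. The 23 platelet-like cells held Clec1b at 6301 CPM and the platelet chemokine gene Pf4 at 23456 CPM. The 38 basophil-like cells held Il1rl1 at 90.6 CPM. An unnamed cluster of 189 cells held the proliferation gene Mki67 at 921 CPM, with the macrophage gene Chil3 at 9374 CPM and Clec1b at 60.4 CPM. In it 100% of cells had a UMI of Ptprc, the CD45 gene, and 81.0% one of Epcam. An unnamed cluster of 187 cells held Dntt, the gene of a nucleotide transferase of immature lymphocytes, at 222 CPM, with Cd3e at 303 CPM and Rag1 at 52.2 CPM. It made up 2.08% of the cells of the library with CD45-positive cells of F1 and 0.239 to 0.743% of the other 6. An unnamed cluster of 52 cells held the cartilage collagen gene Col2a1 at 4582 CPM, with Cytl1 at 39771 CPM and Chad at 7051 CPM.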

How the results depend on the processing

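Alternatives chosen only after the data were seen were leaving out the library with the highest free RNA share of a single class (9.96%, in mesothelial cells), library totals alone, the crossed replicate block, the ungrouped filter and a correlation between the fractions of a code. Over 257 results and 27 alternative settings, 3476 values were computed. Of 823 alternative values of genes named for AT2 against AT1, 784 kept their direction and side of the threshold, 24 fell below it, 6 rose past it and 9 reversed. For genes named within a class between M and F the counts were 1192, 230, 17 and 1 of 1440, across fractions 198, 13, 13 and 1 of 225, and for Il33, Pdpn, Clec1b and Il1rl1 by class 419, 28, 6 and 5 of 458. Depth limits AT1 cells (206), mesothelial cells and genes with few counts. Except where stated, the cause was not tested.

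A minimum of 500 UMIs gave Il33 in ciliated cells −1.39, Clec1b in interstitial macrophages 1.70 and an AT1 share difference of 0.112. A minimum of 2000 gave Il33 −2.68 in club and −1.41 in ciliated cells and Clec1b 1.41 in interstitial macrophages. Without doublet removal, Il33 was −2.48 in club and −1.46 in ciliated cells, Clec1b 1.02 in interstitial macrophages, Pf4 in fibroblasts 0.39, calls higher in M numbered 102, and share differences were 0.437 for ciliated and −0.0202 for B cells. For Clec1b in interstitial macrophages a Leiden resolution of 0.5 gave 1.45, a resolution of 2 gave 1.21, a limit of 10% mitochondrial UMIs 1.39 and no block 1.97. A resolution of 2 also gave Il1rl1 0.60 in interstitial macrophages and 0.18 in T cells. DESeq2 gave Clec1b −0.00879 in monocytes and −1.59 in T cells, and Il1rl1 0.71 in plasma and 1.01 in T cells. Without the filter Il33 in lymphatic endothelial cells passed at 1.29, calls numbered 496 higher in M and 890 in F, and 0 genes passed for library set. Without the replicate block Xist was 0.0125 between AT2 and AT1.

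Across fractions, sums over all cells gave 14 genes, 5 of them outside the sex-chromosome list, 2 for library set and Lpcat1 at −0.0118. A prior count of 0.5 gave 0 genes for library set, and the ungrouped filter 1 gene between M and F: Eif2s3y, Kdm5d, Uty and Tsix were not tested, and Eif2s3x had an adjusted p of 0.0760. Without that library of 9.96% free RNA in mesothelial cells, Pdpn was −2.37 in AT2 cells and −3.54 in pericytes or smooth muscle cells, Clec1b 1.86 in interstitial macrophages, 1 gene outside the list passed and 0 for library set. Library totals alone gave 1419 and 4302 genes for AT2 and AT1 (1222 and 3907 outside the clustering genes), a median of −0.54, Cd44 −0.24, Irak2 −0.30, H2-Ab1 −0.00826, Hsp90aa1 −0.54 and Krt18 −0.52. This shift follows from the scaling itself. Camera with an estimated correlation called 0 lists for AT2 against AT1 and 0 between M and F. Thinning to 500 UMIs gave shares of 15.2% for Il33 in AT2, 41.6% for Pdpn in AT1, 3.14% for Clec1b in alveolar macrophages and 18.9% for Il1rl1 in ILC2. Unthinned shares were 88.6, 87.1, 54.0 and 77.7%, and 61.5% for Il33 in mesothelial cells.

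By the labels, codes of the same number share libraries, in opposite fractions. Within classes they deviated together with a median r of 0.0166 over classes (−0.166 to 0.121). With the replicate block, 178 calls were higher in M and 376 in F, and across fractions 11 genes passed, 2 outside the list and 2 for library set. The crossed pairing gave 155 and 316. A correlation between the fractions of a code, estimated at 0.0369, changed no count across fractions.

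Leaving out 1 code at a time, the log2 differences ranged as follows. Il1rl1 went from −3.76 to −2.67 in alveolar macrophages, −2.58 to −2.22 in monocytes, −2.04 to 1.77 in plasma cells, −0.38 to 1.5 in neutrophils and 0.68 to 1.60 in T cells. Without M1, M2 or F2, plasma cells had 2 codes. Some of these fits had no usable SE: without M1 that of Il1rl1 was 2.91e+06 in alveolar macrophages and 2.58e+06 in monocytes. An end of a range can come from such a fit, as −2.58 in monocytes does. Il33 went from −7.98 to −2.0 in ciliated, −2.76 to −1.11 in blood endothelial, 0.14 to 2.39 in lymphatic endothelial and −5.00 to −3.30 in pericytes or smooth muscle cells. It went from 5.74 to 6.82 in AT2, 3.86 to 5.22 in mesothelial cells and 1.74 to 2.79 in fibroblasts. Clec1b went from 1.85 to 2.36 in interstitial macrophages and 1.79 to 2.99 in neutrophils. Pdpn went from −3.53 to −2.14 in AT2 and −4.42 to −3.38 in pericytes or smooth muscle cells. Between AT2 and AT1, Ifi27l2a went from −1.23 to 0.99, Cd44 from −0.24 to 1.91 and Mki67 from −0.0515 to 2.54. Calls between M and F went from 142 to 313 higher in M and 193 to 797 in F. Across fractions 6 to 20 genes passed, 0 to 14 outside the list and 0 to 7 for library set.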

Other observations

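Chosen only after the result was seen were the tests of interferon genes across fractions, of Clec1b against the other classes, and of M versus F calls after subtraction of free RNA.

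Interferon response genes, a list fixed in advance, lay lower in M than in F in every one of the 14 classes by their median, from −0.80 to −0.08 on the log2 scale. The classes come from the same 4 codes and share libraries, so they are not independent repeats. Across fractions 17 of 20 measured members were below 0 and 15 were so in both fractions. The median difference was −0.43, with −0.29 in CD45-positive and −0.38 in CD45-negative cells. Mean log2 CPM of the list in CD45-positive cells was 3.24 in M1, 3.18 in M2, 3.36 in F1 and 3.74 in F2. In CD45-negative cells it was 2.57, 2.78, 3.02 and 3.06. Isg15, an ubiquitin-like antiviral gene, differed by −0.49, the interferon regulator gene Irf7 by −0.66 and the nucleic acid sensor gene Zbp1 by −0.58, examples picked after their values were seen. None passed over all genes with limma (12 passed adjusted over the list alone). Fry gave an adjusted p of 0.0920 for 1 direction and 0.00416 for either (0.0980 and 0.00453 with the fractions of a code correlated), and adjusted p = 0.253 with an estimated correlation. For the library-set term 12 members were below and 8 above 0, with a median of −0.01 (fry adjusted p = 0.968). Leaving out a code at a time left 15 to 18 of 20 below 0, with medians from −0.49 to −0.41.

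Alveolar macrophages held RNA of genes usually followed in epithelium, an observation made after the values were seen. Epcam, the adhesion gene whose product was stained for the sort, stood at 173 ± 48.2 CPM in alveolar macrophages and 130 ± 23.6 CPM in dendritic cells (SD, n = 4 codes), beside 254 ± 11.7 CPM in AT2 cells. It stood at 25.4 ± 4.25 CPM in B cells and 1.07 ± 0.272 CPM in fibroblasts. Pdpn stood at 15.4 CPM and Il33 at 0.411 CPM in alveolar macrophages, while the empty droplets held more Il33 than Pdpn, at 39.8 to 63.6 and 14.8 to 25.9 CPM. The cycling cluster described by Mki67 held Pdpn at 8.95 CPM.

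Clec1b in alveolar macrophages is a first pattern to weigh, since the gene is best known from platelets. If platelets had left their RNA, 15 fixed platelet markers would stand in macrophages in the ratio to Clec1b that they have in platelet-like cells. Their median accounted for a share of 0.0170 of it (interval 0.00889 to 0.0309), with Pf4, the most abundant of them, at 10.5 CPM against 23456 CPM in platelet-like cells. Free RNA would give the CD45-positive classes a like level, but alveolar macrophages lay at least 13.4 times (up to 26.9 times, over 4 codes) above the median of the other classes. Transcription of Clec1b in these cells is a candidate explanation, a hypothesis for which no group of the design gave a test.

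Il33 in mesothelial cells is a second pattern. RNA of AT2 cells, free or in doublets, would bring 25 fixed AT2 markers along, but their median accounted for a share of 0.00284 of the Il33 (interval 0.00173 to 0.0133). Sftpc, the most abundant of them, stood at 195 CPM in mesothelial and 201380 CPM in AT2 cells. A mixture with other cells would leave cells with an Il33 UMI poorer in mesothelial markers, but their mean marker level was 0.947 of that in cells without one (interval 0.822 to 1.09, 122 cells). The mesothelial cells may themselves transcribe Il33, a hypothesis for which no group of the design gave a test.

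The M versus F calls outside the sex-chromosome list are the third. Free RNA would give calls the direction of the empty droplets, and a share of 0.745 of 192 calls had it (interval 0.677 to 0.805), the side written in advance for free RNA; but empty-droplet RNA comes from the same cells, so a true difference would leave the same trace. Subtracting free RNA at its estimated share left a share of 0.917 of calls past the threshold in their direction (interval 0.868 to 0.952), with a median absolute log2 fold change of 1.10 before and 1.14 after, which argues against free RNA at that share as the whole cause. A difference between the library sets would reverse signs between fractions, and genes called in CD45-positive classes had the same sign in the CD45-negative classes in a share of 0.508 (interval 0.417 to 0.598, 126 genes), which leaves library set and letter open, and they cannot be told apart for these genes. M and F codes did differ in Xist and in the Y-linked genes, without overlap in 19 of 19 classes. Whether sex, or another trait that goes with the letters, gave the other calls was not tested.

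Other splits of the sums were counted as well. For AT2 against AT1, 1 of 35 splits of the 8 sums into 4 and 4 gave as many genes as the real one, the real one itself, with 5017 genes without the block and at most 3 in the others. The classes were made from expression, so the real split was bound to stand out and its count is no test of it. With the code as a block, 8 splits part the sums of every code, with 4636 genes in the real one and 0 in the others, and so few splits cannot give a share under 0.05. For M against F across fractions, 2 of 3 splits of the 4 codes gave at least as many genes, with 6 in the real one and 21 for M1 and F1 against M2 and F2. That split follows the number, which marks shared libraries, and points to a structure of the samples; with the number as a block 11 genes passed between M and F. So few splits here cannot give a share under 0.05.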
